A study of Mus musculus with 2 samples.

How the data were processed

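Spatial gene expression was measured in 2 heart sections, 1 from a C57BL/6J mouse injected with LCWE, a cell wall extract of Lactobacillus casei that causes vasculitis in mice, and 1 from a mouse injected with PBS. Hearts were taken 1 week after injection and cut at 10 µm. Each section lay on a Visium slide, on which spots carrying barcoded primers capture the polyadenylated RNA of the tissue above them, so that each unique molecular identifier (UMI) counts 1 captured molecule at 1 spot. A spot covers several cells of different types, and no cell type makeup of spots was estimated.

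The authors' deposited matrices hold raw UMI counts per gene and spot, not normalized, made with Space Ranger 1.0.0 according to the file headers. The submitters' processing notes also name bcl2fastq 2.20 and the mouse build mm10. Each library was counted separately, and the deposited matrices hold 1195 spots of the LCWE section and 2032 spots of the PBS section. A deposited table assigns 683 and 1803 of these spots to 3 clusters, numbered 0, 1 and 2 by the authors, and its counts per spot equalled the sums of the matrices. The filter that removed the other spots and the clustering settings are not given in the sources used here. Position of spots on the slide was not used here. Other deposited copies of the counts held the same values for the spots they cover and were not used.

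The matrices list 31053 features with 31017 distinct symbols, and features that share a symbol (71 features) were summed. Gene positions were taken by symbol from a RefSeq table of GRCm38.p6, the assembly that mm10 names, in which 25166 of the symbols were found. UMIs were summed over the spots of a section, or of a region of a section, and divided by the summed UMIs of all genes, with the usual scaling, to give CPM. The ratio of CPM, LCWE over PBS, was given the exact conditional (Clopper-Pearson) 95% interval, single CPM values the exact Poisson interval and shares of spots the exact binomial interval. All of these cover counting error only. With 1 section per group no test between treatments exists, no p-value was computed, and each difference is a difference between 2 sections. Where a gene had no UMI in 1 section, a fold was computed against a floor of 3 counts over that section or region and is given as "at least". A share or level of 0 is given with the limit that 3 counts would set.

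The following choices were fixed before the data were examined. Genes with at least 100 UMIs over both sections were counted where the CPM ratio was at least 2-fold. The genes named for the whole section had a UMI in at least 20 spots of the higher section, and were the 15 highest and the 15 lowest by the bound of the interval nearest to 1. Mitochondrially encoded genes, genes of ribosomal proteins, sex-linked genes and gene models without a proper symbol were left out. Within a region the minimum was 50 UMIs and 5 genes were taken in each direction. Another 14 genes were always reported, and from each list up to 4 members were taken by the same bound. Altogether 43 lists of 468 genes covered cell types, pathways and checks of quality. A list member counted as measured from 20 UMIs over both sections, and as higher or lower from 1.5-fold with an interval excluding 1. Each list of at least 3 measured members has a median log2 ratio, an interval from 500 Poisson redraws of its counts, and the percentile of the median among 10000 random lists of the same size drawn from 20 bins of mean expression. Percentiles describe these 2 libraries and are not tests. The authors' clusters served as regions and were compared where each section had at least 20 spots. For shares of spots with a UMI of a gene, each spot was thinned to 8100 UMIs, the 10th percentile of the shallower section rounded down, and 118 LCWE and 183 PBS spots below that depth were left out.

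The scaling between the sections mattered. Mitochondrially encoded genes took 24.8% of UMIs in the LCWE section and 36.0% in the PBS section, and the 10 most abundant genes took 27.9% and 37.7%. On the CPM scale the median gene with at least 20 UMIs had a log2 ratio of 0.38 over the whole sections, 0.22 in region 0, 0.11 in region 1 and 0.20 in region 2. List medians are given relative to that median of all genes. Values of single genes are CPM and ratios of CPM, without this subtraction. TMM factors (edgeR 4.0.16, R 4.3.3) and DESeq2 1.42.0 size factors were computed on the sums as alternatives, without any test by those tools. TMM shifted the median of the genes with at least 100 UMIs from 0.36 to -0.04, and scaling without mitochondrially encoded genes shifted it to 0.13.

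Other alternatives were scaling without mitochondrially encoded genes, equal weight for each spot, spots with at least 500 UMIs, equal weight for each region, thinning of the PBS section to the LCWE total, other minimums of UMIs (30 and 300 for genes, none and 100 for list members), and spots clustered anew. That clustering used scanpy 1.11.5 on both sections together, with counts scaled to 10000 per spot and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. It gave 9 clusters, each matched to the authors' region holding most of its annotated spots, and 96.4% of annotated spots fell in the matching region, although each cluster held mainly spots of 1 section. Other resolutions were planned only in the absence of an annotation. Analyses limited to annotated spots, and region 2 compared in bins of its share of contractile RNA, were added after the data had been seen. No doublet caller was run, since spots are not cells. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

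The ratio and interval calculations were tested on simulated data. Poisson counts were drawn for the whole-section comparison from the real means and totals, with 200 of the 11799 genes altered. Of the 50 genes in each class, 100% of those raised or lowered 4-fold and 100% of those raised or lowered 3-fold passed the 2-fold line. Intervals held the true ratio for 95.7% of the 11599 unaltered genes and for 90.0% to 100% of the genes of each altered class. None of the unaltered genes passed the line (0%). Apart from the altered genes, both simulated sections shared pooled rates, with no difference in mouse, plane of section or mix of regions. These figures therefore cover counting error only.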

Results

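Gene expression was mapped in 1 heart section from a mouse given LCWE, which induces vasculitis resembling Kawasaki disease, and in 1 heart section from a mouse given PBS, 1 week after injection. The LCWE section held 1195 spots with 20369383 UMIs in total and a median of 17610 UMIs per spot. The PBS section held 2032 spots with 37083301 UMIs in total and a median of 19330 per spot. There was 1 section per treatment, so every interval below covers counting error only, and mouse, treatment and plane of section differed together. The summed CPM of the adipocyte list was 20.9 in the LCWE section and 248.4 in the PBS section.

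The first comparison asked how the LCWE section as a whole differed from the PBS section. By the fixed rule the gene furthest above the PBS section was Saa3, which encodes an acute-phase serum amyloid A protein. It stood at 519.5 CPM in the LCWE section and 0.0539 CPM in the PBS section, where 2 UMIs were counted (9632-fold, 2666 to 79549). S100a8 and S100a9, the calprotectin subunits carried by neutrophils and monocytes, were 132-fold (86.7 to 211) and 95.9-fold (66.9 to 143) higher. The neutrophil-attracting chemokine Cxcl5 was 191-fold higher (92.4 to 478) and the B cell chemokine Cxcl13 192-fold higher (74.3 to 707). Genes of fat cells were the lowest, with Cidec, which encodes a lipid droplet protein, at 1 UMI against 560 (ratio 0.00325, 0.0000822 to 0.0182) and Adipoq, which encodes adiponectin, 58.3-fold lower in the LCWE section.

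Of 11799 genes with at least 100 UMIs, 1751 were at least 2-fold higher and 124 at least 2-fold lower in the LCWE section, so 93.4% of these differences were on the higher side. After subtraction of the median of all genes, the numbers were 981 and 374 (72.4% higher), and with TMM scaling they were 934 and 436 (68.2% higher). Others among the 15 highest genes by the fixed rule were Il1rn, the interleukin 1 receptor antagonist (11.7 against 0.0270 CPM, the latter from 1 UMI, 435-fold, 77.3 to 17257), Lcn2, the iron-binding lipocalin 2 (111.2 against 1.97 CPM), Serpina3n (781.2 against 13.0 CPM), Mmp3, stromelysin 1 (358.9 against 7.71 CPM), Bmp10, a growth factor of atrial muscle (453.9 against 4.72 CPM), Slfn4 and Crabp2. Of the 9245 Bmp10 UMIs of the LCWE section, with spots clustered anew, 8796 lay in 1 cluster of 388 atrial spots without PBS spots, and in another atrial cluster, number 5, with spots of both sections, Bmp10 was at 33.9 against 12.01 CPM. Sirpb1c, Glycam1 and Serpina3m had no UMI in the PBS section and were at least 91.6-fold, 90.4-fold and 88.6-fold higher. Saa3 lies on chromosome 7 at 46711998 to 46719615 of GRCm38.p6, S100a8 on chromosome 3 at 90669071 to 90670034, and Bmp10 on chromosome 6 at 87428994 to 87434512.

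Markers of immune cells were higher as groups. All 9 measured neutrophil genes and all 8 inflammatory monocyte genes were at least 1.5-fold higher, with list medians 4.21 and 4.37 log2 units above the median of all genes. Examples were Il1r2, the decoy receptor for interleukin 1 (58.3-fold), Ly6c2 (36.2-fold) and Plac8 (33.7-fold). All 14 macrophage genes were higher (median 1.60 above that of all genes), among them Ctss, which encodes cathepsin S (6.99-fold), Fcgr1 (7.31-fold) and Lgals3 (5.42-fold). Higher members made up 9 of 10 dendritic cell genes, 10 of 11 T cell genes, all 4 cytotoxic lymphocyte genes and 7 of 8 B and plasma cell genes. Levels of lymphocyte genes were low, with Cd3e, a chain of the T cell receptor complex, at 1.57 CPM from 32 UMIs against 0.162 CPM from 6 UMIs. With TMM scaling 4 of the 8 B and plasma cell genes remained at least 1.5-fold higher. Mast cell genes were higher in 3 of 5 cases, and in 1 of 5 with TMM scaling.

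All 14 measured genes of interleukin 1 signalling and the inflammasome were higher (median 1.58 above that of all genes, and 11 of 14 with TMM scaling). Il1b, which encodes the cytokine itself, was at 28.1 against 1.13 CPM (24.8-fold, 18.1 to 34.8), Il6 was 54.2-fold higher, and Nlrp3, the inflammasome sensor, was at 1.33 CPM from 27 UMIs against 0.297 CPM from 11 UMIs (4.47-fold, 2.15 to 9.98). Among chemokine genes 21 of 22 were higher (median 3.22 above that of all genes), including Ccl8 (25.3-fold) and Ccl19 (16.9-fold). All 11 complement genes were higher (median 1.87), led by Cfb, complement factor B (45.2-fold), C4b (13.2-fold) and C3 (9.05-fold). All 7 genes of MHC class II presentation (2.60) and all 9 of class I (0.89) were higher, with Cd74, the class II invariant chain, at 1629 against 206.5 CPM. Interferon response genes were higher in 19 of 22 cases (1.12) and endothelial activation genes in 7 of 9 (1.54), among them the adhesion molecules Selp (15.8-fold), Vcam1 (4.91-fold) and Icam1 (4.29-fold). Proliferation genes were higher in 13 of 15 cases (1.21). Each of these medians lay above at least 99.9% of the matched random lists.

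Connective tissue genes were higher as well. Of 18 genes of activated fibroblasts and matrix, 17 were higher (median 1.88 above that of all genes, and 1.13 above it with equal weight for each region), including Timp1, an inhibitor of matrix metalloproteinases (33.6-fold), the collagen cross-linking enzyme Lox (14.1-fold) and Col1a1, a chain of type I collagen (1955 against 256.4 CPM, 7.62-fold). Postn, which encodes periostin, was 2.26-fold higher over the whole section, with ratios of 2.09, 1.29 and 1.12 in regions 0, 1 and 2 and 0.756 in spots without annotation, and a log2 ratio of 0.77 with TMM scaling and 0.25 with equal weight for each region. All 18 matrix remodelling enzymes were higher (1.85), among them Mmp12 (36.3-fold). Of 12 genes linked to phenotype switching of smooth muscle, 11 were higher (1.76), led by Spp1, which encodes osteopontin, at 159.4 against 4.13 CPM. Several of these genes are also made by fibroblasts or macrophages. Contractile smooth muscle genes had a median 0.10 above that of all genes (3 of 12 higher) and 0.79 below it when each region had equal weight, with Myh11 at 28.5 against 33.0 CPM and Acta2 at 296.0 against 210.4 CPM. Resting fibroblast genes were higher in 7 of 12 cases (0.50), and in 5 with TMM scaling. Over the alternatives their median fell to as little as 0.06 above that of all genes. Relative to all genes the medians were 0.80, 0.09 and -0.06 in regions 0, 1 and 2. There 7, 1 and 4 members were higher and 0, 2 and 3 lower.

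Genes of heart muscle and its energy supply had medians below that of all genes. All 17 fatty acid oxidation genes were at least 1.5-fold lower (median 1.23 below that of all genes, below all of the random lists), including Ucp3 (3.39 against 16.5 CPM), Pdk4, which restrains glucose oxidation (41.6 against 128.4 CPM), and Fabp3, the fatty acid binding protein of heart (1704 against 3853 CPM). Lists for the nuclear-encoded respiratory chain and the tricarboxylic acid cycle had medians 0.92 and 0.87 below that of all genes, with 10 of 22 and 4 of 13 members lower, and 22 of 22 and 13 of 13 lower with TMM scaling. Mitochondrially encoded genes had a median 0.90 below that of all genes, with 0 of 13 members passing as lower (13 with TMM scaling), and cardiomyocyte contractile genes 0.79 below it, with 6 of 15 lower (13 with TMM scaling). In regions 0, 1 and 2 the mitochondrially encoded median lay 0.37, 0.17 and 1.95 below that of all genes. With either scaling 0, 0 and 13 of its 13 members were lower there. Respiratory chain medians lay 0.58, 0.52 and 1.47 below, with 0, 2 and 22 members lower (13, 7 and 22 with TMM scaling). Tricarboxylic acid cycle medians lay 0.55, 0.42 and 1.47 below, with 0, 1 and 13 members lower (8, 2 and 13 with TMM scaling). Myh6, the main myosin heavy chain of adult mouse heart, was at 7524 against 8202 CPM. Natriuretic peptide genes, which respond to wall stretch, were higher: Nppa was 1.72-fold higher and Nppb 2.78-fold higher over the whole section (log2 ratio of Nppb 1.47, and 0.88 with equal weight for each region). Within regions this did not hold throughout, with CPM ratios of 1.07, 1.26 and 0.453 for Nppa and 0.917, 2.57 and 0.535 for Nppb in regions 0, 1 and 2, and in the atrial spots of cluster 5 Nppa was lower (34787 against 47410 CPM). The cardiac stress list as a whole lay 0.19 above the median of all genes, with 6 of 12 members higher.

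Other cell type lists give the background to these values. Each of the 7 adipocyte genes was lower, including Cfd, which encodes adipsin (4.61 against 178.5 CPM), Retn and Plin1. Car3, an abundant carbonic anhydrase of fat and muscle, was 74.0-fold lower, and Nnat, Adig, Pon1, Gpr22, Fgf16, Thrsp, Lingo3 and Tfrc, the transferrin receptor, complete the 15 lowest genes. Endothelial genes lay 0.02 below the median of all genes and pericyte genes 0.48 below it. Atrial cardiomyocyte genes lay 0.04 below it, glycolysis genes 0.23 below and circadian genes 0.26 below. Lists for erythrocytes (0.76), platelets (0.80), Schwann cells and neurons (0.86), lymphatic endothelium (0.60), epicardium and mesothelium (0.25), cartilage (0.87) and immediate early and heat shock genes (0.75) lay above it. With equal weight for each region, which also leaves out spots without annotation, the erythrocyte, platelet, epicardial, cartilage, immediate early and heat shock and contractile smooth muscle medians lay below that of all genes (-0.46, -0.22, -0.36, -0.14, -0.10 and -0.79), and the atrial, glycolysis and circadian medians turned from above 0 to below 0 as log2 ratios. Leaving those spots out alone took the erythrocyte median to 0.08 below that of all genes and the atrial log2 median to -0.19. No member of the sex-linked list reached a 1.5-fold difference among the 4 measured. Lists for lung and airway and for thymocytes had 1 and 2 measured members and no median.

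The second comparison used the authors' 3 clusters of spots, called regions here by their leading genes. The leading genes of region 0 in both sections included Myl2, Myl3, Lrtm1 and Irx4, of which Myl2 and Myl3 encode ventricular myosin light chains. Those of region 1 included Nppa, Myl7, Myl4 and Sln, genes of atrial muscle, in both sections. Region 2 was led by Cxcl5, Spp1, S100a8 and Chl1 in the LCWE section and by the connective tissue and smooth muscle genes Chad, Cnn1, Fmod and Comp in the PBS section. In the LCWE section regions 0, 1 and 2 held 32.2% (28.7 to 35.9), 29.4% (26.0 to 33.0) and 38.4% (34.7 to 42.1) of the 683 annotated spots. In the PBS section they held 52.0% (49.7 to 54.4), 35.9% (33.7 to 38.1) and 12.1% (10.6 to 13.7) of the 1803 annotated spots. The shares are given per section only, because the leading genes of region 2 differed, and because 42.8% of LCWE spots but 11.3% of PBS spots were outside the annotation.

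Within the LCWE section most UMIs of several inflammatory lists lay in region 2. That region held 29.1% of the annotated UMIs but 85.5% (84.3 to 86.7) of those of the neutrophil list, 73.5% (73.0 to 74.1) of the chemokine list, 71.8% (70.4 to 73.1) of the interleukin 1 and inflammasome list and 76.8% (76.6 to 77.0) of the activated fibroblast and matrix list. S100a8 and S100a9, which lead the region, gave 1196 and 1115 of its 3015 neutrophil UMIs. Macrophage genes (61.1%, 60.6 to 61.5) and MHC class II genes (60.2%, 59.8 to 60.6) were spread more widely, and the B and plasma cell list had 52.1% (47.9 to 56.3) of its UMIs in region 0 and 35.7% (31.7 to 39.7) in region 2, with Igkc alone giving 190 of the 298 UMIs in region 0. In the PBS section region 2 held 6.78% of the annotated UMIs, 20.9% (20.4 to 21.4) of macrophage UMIs and 34.1% (33.7 to 34.4) of matrix UMIs, while its neutrophil share was 16.9% (11.1 to 24.1) of 142 UMIs.

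**Figure D1:**
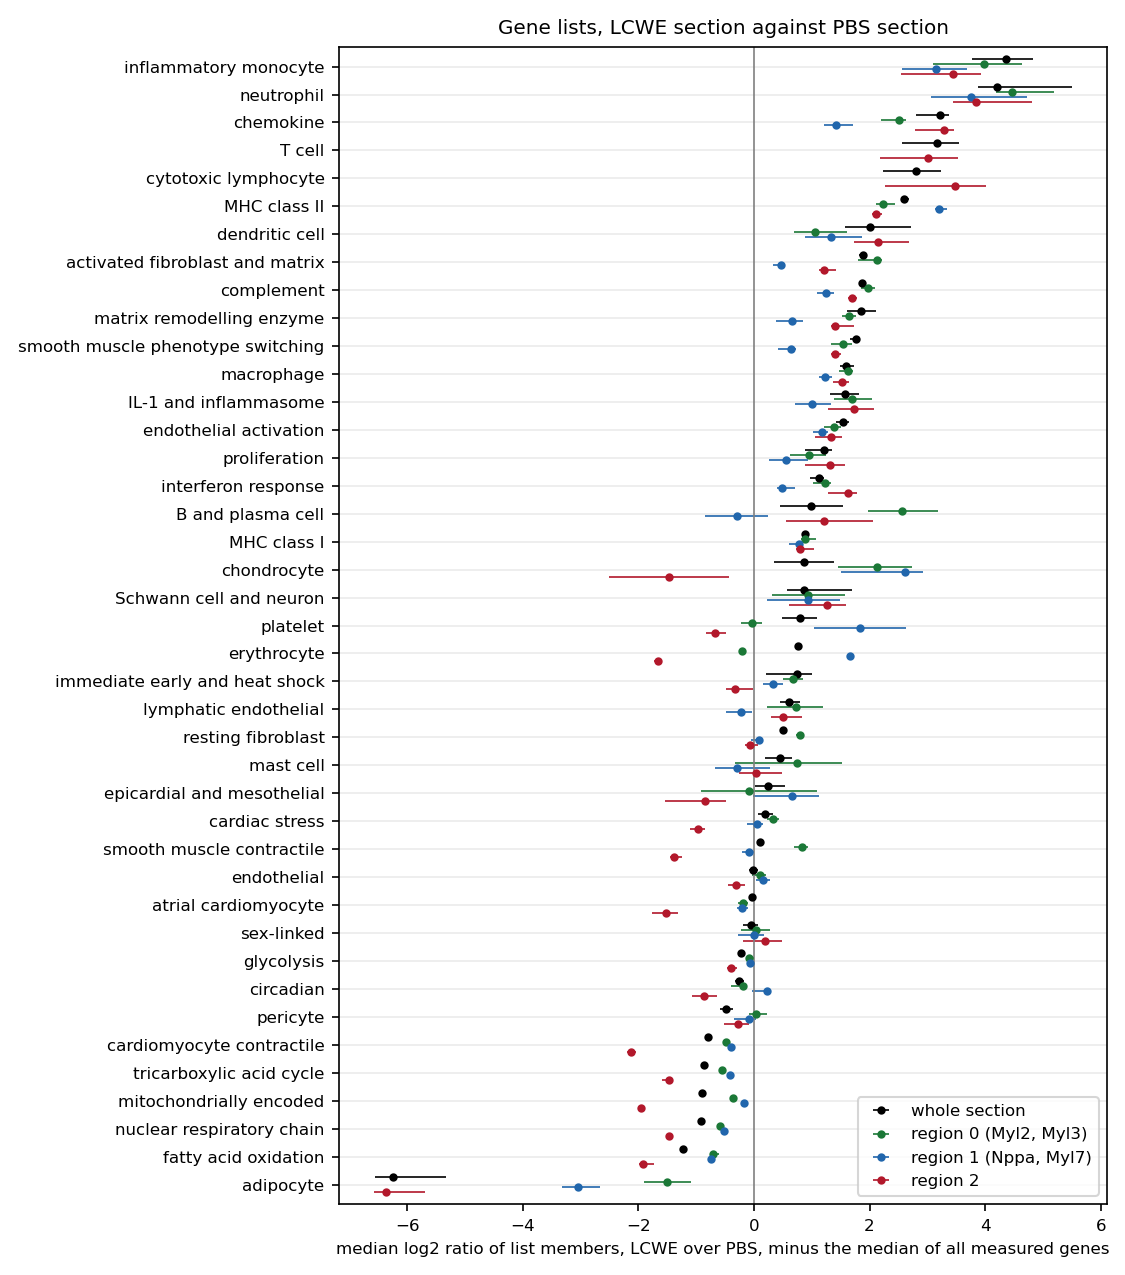
Median log2 ratio of the members of each gene list, LCWE section over PBS section, minus the median of all measured genes (horizontal axis), for whole sections and for regions 0, 1 and 2, with 95% intervals of counting error as bars. The neutrophil list lies farthest to the right in each region, adipocyte and fatty acid oxidation lists lie to the left, and smooth muscle contractile genes lie at 0.83 in region 0 and -1.38 in region 2.

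The third comparison set the same region of both sections side by side. With spots clustered anew, 197 of the 220 LCWE spots of region 0 fell in a cluster with 3 PBS spots of that region, 184 of the 201 LCWE spots of region 1 in a cluster without PBS spots, while 623 of its 647 PBS spots lay in cluster 5, and 226 of the 262 LCWE spots of region 2 in a cluster without PBS spots. In region 0, the ventricular muscle, Saa3 stood at 294.7 CPM in the LCWE section with no UMI in the PBS section, where 3 counts would be 0.152 CPM (at least 1937-fold higher). Serpina3n (107-fold, 86.8 to 133), complement factor Cfb (135-fold, 61.0 to 374), Timp1 (71.1-fold, 60.4 to 84.3) and Ccl8 (74.4-fold, 53.6 to 106) were the other genes named there as higher. All 14 macrophage genes, all 11 complement genes and all 7 MHC class II genes were higher, with medians 1.63, 1.98 and 2.23 above that of all genes. Matrix genes were higher in 17 of 18 cases (2.12), with Col1a1 at 1048 against 109.5 CPM. Contractile smooth muscle genes were higher in 8 of 12 cases and lower in 1 (0.83). Among the higher were Cnn1 (3.86-fold) and Acta2 (2.36-fold), whereas Myh11 at 1.32-fold (1.02 to 1.70) did not reach 1.5-fold. B and plasma cell genes reached a median 2.57 above that of all genes over 4 measured members, with the immunoglobulin light chain gene Igkc at 42.3 against 3.09 CPM. Igkc is also among the leading genes of this region in the LCWE section.

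Muscle genes of region 0 were nearer to the PBS level. Fatty acid oxidation genes had a median 0.70 below that of all genes (3 of 17 at least 1.5-fold lower, and 11 with TMM scaling), with Acadm, which encodes medium-chain acyl-CoA dehydrogenase, at 358.5 against 554.5 CPM. Contractile genes had a median 0.48 below, and Myh6 was at 6245 against 7204 CPM. The stress-responsive gene Ankrd1 was 2.94-fold higher and the skeletal actin gene Acta1 1.99-fold higher, whereas Nppb was at 77.9 against 85.0 CPM, with an interval of the ratio that held 1. Genes named as lower were Cfd, Car3, Drd2, the transcription factor gene Irx5 (0.668 against 5.27 CPM) and Cenpf. Of genes with at least 100 UMIs in the region, 841 were at least 2-fold higher and 74 lower (91.9% higher), or 525 and 173 (75.2% higher) with TMM scaling.

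In region 1, the atrial muscle, the LCWE section again had more transcripts of antigen presentation and complement. Cd74 was at 1203 against 120.3 CPM (10.0-fold, 9.44 to 10.6), H2-Ab1 was 10.7-fold higher, and all 7 MHC class II genes (median 3.21 above that of all genes), all 11 complement genes (1.24) and 13 of 14 macrophage genes (1.23) were higher. Saa3 was at 103.5 CPM and had no UMI in the PBS region (at least 430-fold higher). Cxcl13 was 183-fold higher (61.8 to 896), Serpina3n 44.0-fold and the immunoglobulin gene Iglc1 82.3-fold (21.8 to 695, from 2 PBS UMIs). The B and plasma cell list was not higher as a group, with a median 0.30 below that of all genes. Of its 4 measured members 1 was higher and 1 lower. Fatty acid oxidation genes were lower in 11 of 17 cases (median 0.75 below), with Pdk4 at 29.7 against 152.7 CPM. Matrix genes were higher in 9 of 18 cases (0.47). In the atrial spots of cluster 5 of the new clustering (41 LCWE and 709 PBS spots), 3 of 17 fatty acid oxidation genes were lower. Their median log2 ratio was -0.26 against -0.64 in region 1. Higher there were 8 of 14 macrophage genes (0.87 against 1.34) and 8 of 10 complement genes (0.99 against 1.35). The same held for 6 of 6 MHC class II genes (2.45 against 3.32). The size of these medians therefore depends on the atrial spots compared. Counts of members passing also depend on depth, since the LCWE spots of cluster 5 held 679154 UMIs against 4475458 in region 1. Of adipocyte genes, 1 of 5 was lower in cluster 5 against 4 of 5 in region 1. Their summed CPM ratio in cluster 5 was still 0.508 (0.289 to 0.832), so these counts do not decide whether that difference depends on the spots.

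Bmp10 stood out in region 1. This growth factor gene, which is among the leading genes of the region in the LCWE section, was at 1156 against 11.5 CPM (101-fold, 85.4 to 120). In the atrial spots of cluster 5, Bmp10 was at 33.9 against 12.01 CPM and Timp4 at 35.3 against 32.0 CPM, so these values depend on which atrial spots the annotation holds. Among the genes named as lower were Timp4, an inhibitor of metalloproteinases (15.8-fold), Ddit4l (1 UMI against 121, ratio 0.0230, 0.000579 to 0.131), Car3 and Cfd. Erythrocyte genes were all higher in this region (5 of 5, median 1.66 above that of all genes), but 0 of 5 were higher in the atrial spots of cluster 5. In region 1, 342 genes were at least 2-fold higher and 102 lower (77.0% higher), or 266 and 150 (63.9% higher) with TMM scaling.

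In region 2 the LCWE section had far more transcripts of neutrophils, cytokines and matrix. Saa3 reached 2128 CPM against 0.427 CPM from 1 UMI (4988-fold, 895 to 197043), S100a8 324.4 CPM against no UMI (at least 253-fold), and S100a9 302.5 against 0.427 CPM (709-fold, 127 to 28027). Cxcl5 was 397-fold higher (70.9 to 15696), and the immunoglobulin A gene Igha was at least 68.9-fold higher. Il1b was at 117.5 against 4.27 CPM (27.5-fold, 14.8 to 57.8), Il1rn 112-fold higher (19.8 to 4445) and Spp1 15.1-fold higher (12.5 to 18.4). S100a8, S100a9, Cxcl5 and Spp1 lead this region in the LCWE section, so their values there partly follow from how spots were assigned. All 7 neutrophil genes (median 3.85 above that of all genes), 21 of 22 chemokine genes (3.28), 13 of 14 macrophage genes (1.53), 11 of 13 interleukin 1 and inflammasome genes (1.74) and 15 of 18 matrix genes (1.21) were higher. Postn, in contrast, was at 618.0 against 553.4 CPM.

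Smooth muscle and heart muscle transcripts of region 2 were lower in the LCWE section. Of 12 contractile smooth muscle genes 10 were lower (median 1.38 below that of all genes), with Myh11, smooth muscle myosin, at 54.0 against 240.6 CPM and Acta2, smooth muscle actin, at 588.9 against 1218 CPM. Endothelial and pericyte medians lay 0.32 and 0.28 below that of all genes. All 15 cardiomyocyte contractile genes were lower (2.13 below), their summed CPM being 8611 against 32800, and mitochondrially encoded genes took 5.17% against 17.3% of UMIs. All 17 fatty acid oxidation genes were lower (1.93 below). Cidec, Cfd, Adipoq, Car3 and Retn were the genes named as lower, all of them abundant in fat. With 955 genes at least 2-fold higher and 546 lower, 63.6% were higher, or 53.7% (764 and 658) with TMM scaling.

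**Figure D2:**
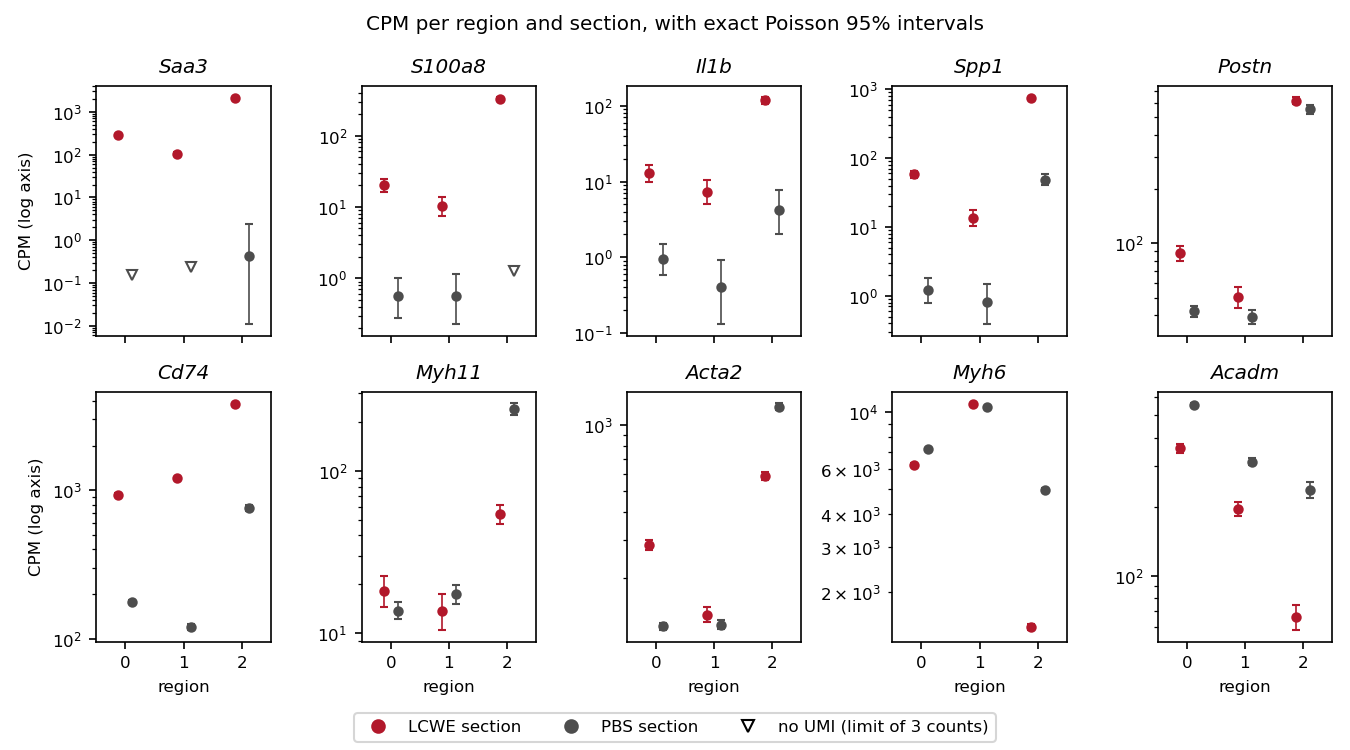
CPM (vertical log axis) of 10 genes in regions 0, 1 and 2 (horizontal axis) of the LCWE section and the PBS section, with exact Poisson 95% intervals; open triangles mark the limit of 3 counts where no UMI was seen. Saa3, S100a8, Il1b, Spp1 and Cd74 are higher in every region of the LCWE section, whereas Myh11 is higher in region 2 of the PBS section (240.6 against 54.0 CPM).

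The share of spots holding a transcript showed how widely the differences reached. After thinning to 8100 UMIs, 22.6% (20.1 to 25.2) of 1077 LCWE spots and 0.595% (0.297 to 1.06) of 1849 PBS spots held S100a8, and 12.3% (10.4 to 14.4) against 0.919% (0.536 to 1.47) held Il1b. Spp1 was seen in 24.2% (21.7 to 26.9) against 1.78% (1.23 to 2.50), Cd68, a macrophage gene, in 28.4% (25.7 to 31.2) against 8.98% (7.71 to 10.4), and Col1a1 in 95.5% (94.0 to 96.6) against 66.5% (64.3 to 68.7). Shares were 13.6% and 13.3% for Myh11, with overlapping intervals, and 1.02% (0.511 to 1.82) and 0.325% (0.119 to 0.705) for Nlrp3, also with overlapping intervals. Without thinning the shares for S100a8 were 29.8% and 0.935%, those for Il1b 19.9% and 1.97%, those for Spp1 37.7% and 3.30%, those for Cd68 44.9% and 19.3%, those for Col1a1 99.6% and 87.1%, those for Myh11 25.6% and 25.3%, and those for Nlrp3 2.09% (1.36 to 3.07) and 0.541% (0.271 to 0.967), where the intervals were apart. Of the 14 genes fixed for this comparison, 10 had an LCWE interval wholly above the PBS interval.

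Spots outside the annotation were compared on their own, 512 of the LCWE section and 229 of the PBS section. Haemoglobin genes took 1.83% and 1.92% of their UMIs, against 0.367% and 0.288% in annotated spots, and the adipocyte list was at 1785 CPM in the PBS spots. The atrial gene Myl7 was at 10790 against 5679 CPM and the ventricular gene Myl2 at 669.9 against 4357 CPM, so these spots were not compared like for like. Here Saa3 (123.1 against 0.394 CPM), Bmp10 (486.2 against 7.10 CPM) and Serpina3n were higher in the LCWE section. The inducible heat shock genes Hspa1a (211.0 against 8.68 CPM) and Hspa1b (132.1 against 9.07 CPM) completed the higher genes named by the rule, and the lower genes named were Car3, Cfd, Cidec, Retn and Adipoq.

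**Figure D3:**
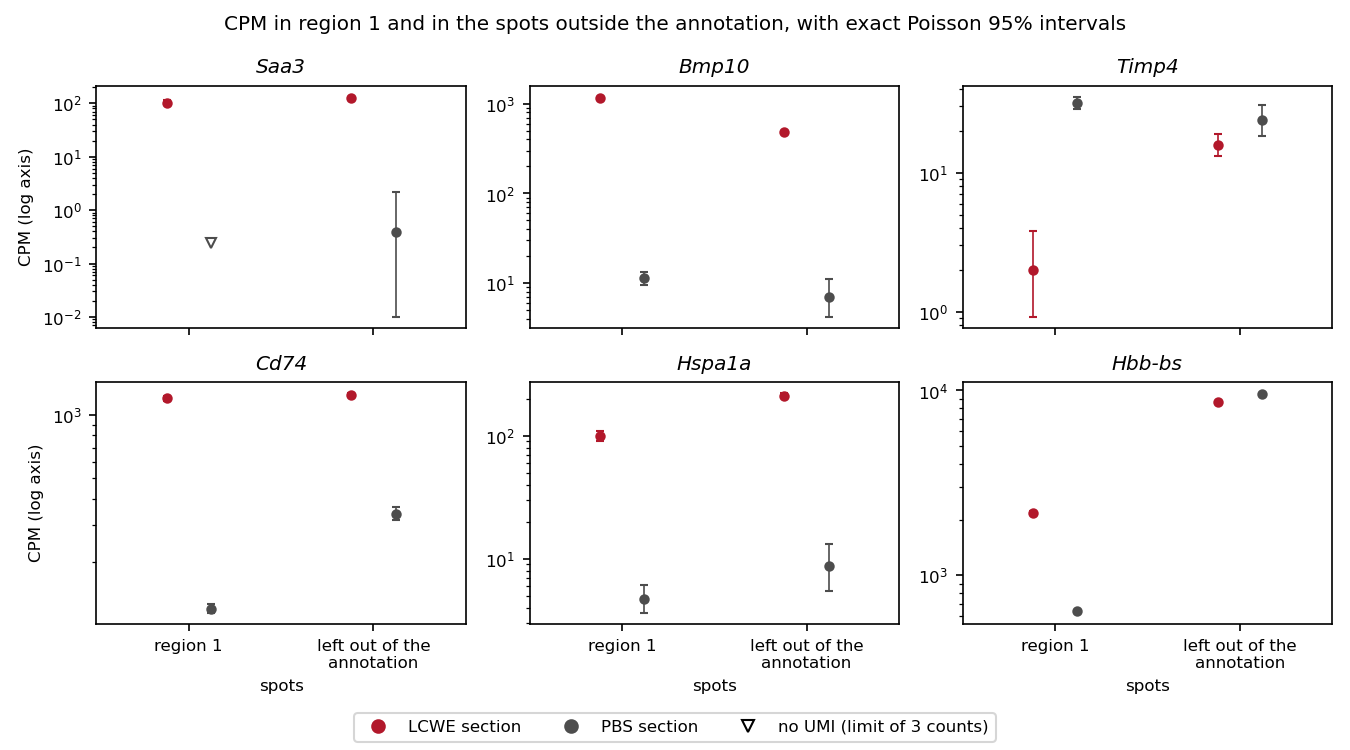
CPM (vertical log axis) of 6 genes in region 1 and in the spots outside the annotation (horizontal axis) of the LCWE section and the PBS section, with exact Poisson 95% intervals; the open triangle marks the limit of 3 counts where no UMI was seen. Saa3 has no UMI in region 1 of the PBS section and 103.5 CPM in region 1 of the LCWE section.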

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

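Of the tests described in this part, the one on the richest spots was chosen before its result was seen and the one on dilution after it. Several lists had medians at least 1.5-fold apart from the PBS level in opposite directions in 2 regions. These differences between regions were not tested, because each region has 1 section per treatment. Medians here are log2 ratios of CPM, LCWE over PBS, with intervals of counting error.

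Contractile smooth muscle genes had a median of 1.05 (0.91 to 1.15) in region 0 and -1.18 (-1.25 to -1.04) in region 2. Dilution of region 2 by RNA of incoming cells, taken as the whole reason, would lower all resident cell types alike if like spots were compared. The endothelial median lay 1.06 (0.87 to 1.20) above the smooth muscle median and the pericyte median 1.10 above it. Like spots were not compared, however. With spots clustered anew, 226 of the 262 LCWE spots of region 2 fell in a cluster without PBS spots. Cnn1, a member of the smooth muscle list, is also among the leading genes of region 2 in the PBS section. These differences therefore do not decide about dilution. In the 20 spots richest in these transcripts their mean CPM was 24132 in the LCWE section and 31435 in the PBS section, a ratio of 0.768, but 12 of those LCWE spots were outside the annotation, so this comparison does not decide about region 2. Dilution, fewer spots over vessel wall and a lower level per smooth muscle cell after LCWE all stay open, since plane of section and treatment cannot be separated with 1 section each.

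The erythrocyte list had a median of 1.77 (1.72 to 1.82) in region 1 and -1.46 (-1.53 to -1.38) in region 2. Both depended on the choice of spots: the median was 0.30 (0.16 to 0.45) in the atrial spots of cluster 5 of the new clustering, -0.64 in its clusters 3 and 5 together and 0.24 in region 2 spots matched for contractile share. For the cartilage list the medians were 2.35 (1.68 to 2.95) in region 0, 2.73 (1.61 to 3.04) in region 1 and -1.27 (-2.31 to -0.24) in region 2. They rest on 4, 3 and 5 measured members, of which 1, 1 and 3 were lower. In region 2 Chad and Col2a1 were among the 3 lower members, and Comp and Acan were higher. Comp is also a member of the activated fibroblast and matrix list. Epicardial and mesothelial genes had a median of 0.77 (0.10 to 1.24) in region 1 and -0.65 (-1.33 to -0.28) in region 2.

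In spots that the annotation leaves out, the heat shock gene Hspa1a was at 211.0 CPM (200.9 to 221.5) in the LCWE section, above the 81.0 CPM of its annotated spots and the 8.68 CPM of the PBS spots left out. Annotated LCWE spots were also above annotated PBS spots (5.62 CPM), so the difference was not particular to the spots left out. Cluster 3 of the new clustering, with 181 LCWE spots of which 180 were left out, held 1132 Hspa1a UMIs (361.9 CPM), against 1628 in all LCWE spots left out.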

How the results depend on the processing

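Scaling and the choice and weighting of spots moved the number of genes past 2-fold. The 1751 higher and 124 lower genes became 934 and 436 with TMM, 934 and 435 with median-of-ratios scaling and 1041 and 200 with equal weight for each region, which uses annotated spots only. Annotated spots without that weighting gave 2148 and 131. The lower genes became 247 without mitochondrially encoded genes in the scaling, 244 and 79 with minimums of 30 and 300 UMIs, and 64 when the interval had to lie beyond 2-fold. The cause of the region effect was not tested, whereas TMM and median-of-ratios scaling shift all log2 ratios by -0.40. All 30 named genes stayed at least 2-fold apart in the same direction over the whole sections in each scaling and weighting, with thinning, with spots of at least 500 UMIs and over annotated spots. With the fixed genes added, 36 of 38 past 2-fold stayed past it in all of these, the exceptions being Nppb (log2 0.88 with equal weight for each region) and Postn (0.25, and 0.77 with TMM). Single clusters were not part of that check, and the size of Bmp10 depended on them (33.9 against 12.01 CPM in cluster 5). At least 1.5-fold higher were 27 of 41 lists (19 to 27 over the alternatives). At least 1.5-fold lower were 2 lists, and 6 with TMM, 6 with median-of-ratios scaling, 6 without mitochondrially encoded genes and 5 over annotated spots alone, an alternative added after the data were seen. Of the 29 lists past 1.5-fold, 26 kept their direction in all alternatives and 21 stayed past 1.5-fold in all. The others were the cartilage, epicardial, erythrocyte, immediate early and heat shock, lymphatic endothelial, mast cell, platelet and resting fibroblast lists. With equal weight for each region the median turned to -0.19 for epicardial and mesothelial genes, -0.29 for erythrocyte genes and -0.058 for platelet genes, and contractile smooth muscle genes went from 0.49 to -0.62 and atrial genes from 0.34 to -0.23 (-0.19 over annotated spots alone), and the cause was not tested. TMM also took atrial (-0.063), circadian, endothelial, glycolysis and sex-linked genes below 0. Pairs of region and list past 1.5-fold numbered 62 higher and 16 lower of 119, with 59 to 68 and 13 to 20 over the alternatives. In region 2, spots matched for contractile share (61 LCWE and 66 PBS spots holding 1% to 2%, the only bin with enough spots, also chosen after the data were seen) turned the erythrocyte median to 0.24 and the cardiac stress median to 0.75, and the cause was not tested. Shares of spots per region stayed within their intervals with spots clustered anew. Among the 14 fixed genes, 10 were in more LCWE spots, 11 without thinning and 9 with thinning to 500 UMIs. Depth limits Cd3e and Nlrp3 most, with 32 and 27 UMIs in the LCWE section. No paired analysis was possible because each group has 1 section.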

Other observations

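Of the tests in this part, those on the macrophage, fatty acid oxidation and mitochondrially encoded lists in clusters 3 and 5 together were chosen before their results were seen, and the others, including all within cluster 5 alone, after.

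Clustering all spots anew divided the atrial spots of the LCWE section into groups that differ in Bmp10. One cluster of 388 LCWE spots, of which 185 were annotated and 203 were not, had Bmp10 at 1215 CPM and Timp4 at 1.80 CPM, and held no PBS spot. A further 222 LCWE spots, of which 14 were annotated, fell into 2 clusters (numbers 3 and 5) with Bmp10 at 24.4 CPM and Timp4 at 28.4 CPM. Of the PBS section 715 spots fell into those 2 clusters, with Bmp10 at 11.9 CPM and Timp4 at 31.9 CPM. Cluster 3 held 181 of these LCWE spots and 6 PBS spots, and cluster 5 held 41 LCWE and 709 PBS spots. In the LCWE section Atf3 was at 194.0 CPM in cluster 3, 16.2 CPM in cluster 5 and 13.8 CPM in the Bmp10-rich cluster, and Hspa1a at 361.9, 88.3 and 106.2 CPM.

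Region 1 may differ between the sections because the annotation holds other groups of atrial spots in each. Medians in clusters 3 and 5 together were 1.12 (0.99 to 1.28) for macrophage genes against 1.34 in region 1, 2.67 (2.61 to 2.86) for MHC class II genes against 3.32, 1.27 (1.09 to 1.35) for complement genes against 1.35, -0.40 (-0.46 to -0.36) for fatty acid oxidation genes against -0.64 and 0.043 for mitochondrially encoded genes against -0.06, but the sections lie mostly in different clusters of this pair, so these values do not decide. Of the 41 LCWE spots of cluster 5, 28 were outside the annotation and so not part of region 1. Within cluster 5 the MHC class II median was 2.45 (2.25 to 2.57) and the complement median 0.99 (0.87 to 1.15). Both lay beyond 0.5 times the values of region 1. With that limit, this argues against the choice of atrial spots as the whole cause for these lists. For macrophage genes (0.87, 0.63 to 1.10, 8 of 14 higher), fatty acid oxidation genes (-0.26, -0.46 to -0.21, 3 of 17 lower against 11 in region 1) and mitochondrially encoded genes (0.057) the explanation stays open. Mouse and treatment were not separated by any of these values and remain untested.

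Fatty acid oxidation genes had medians of -0.48 (-0.51 to -0.39) in region 0, where 3 of 17 members passed as lower, and -0.64 (-0.69 to -0.57) in region 1, where 11 did, which could reflect less cardiomyocyte RNA per spot. The median minus that of contractile genes was -0.22 (-0.26 to -0.10) in region 0 and -0.35 (-0.40 to -0.28) in region 1 on the log2 scale. In region 1 a smaller share of cardiomyocyte RNA stays open as the whole reason. The difference there was -0.02 (-0.19 to 0.09) in the atrial spots of cluster 5. In region 0 it stays open too, because like spots were not compared. With spots clustered anew, 197 of the 220 LCWE spots of region 0 fell in a cluster with 3 PBS spots of that region. Mitochondrially encoded genes lay 0.33 (0.24 to 0.38) and 0.58 (0.51 to 0.63) above fatty acid oxidation genes in regions 0 and 1. In cluster 5 they lay 0.32 (0.26 to 0.49) above them. None of the fatty acid oxidation genes is mitochondrially encoded, so these differences do not decide about a lower yield of mitochondrial transcripts. Whether LCWE, the state of the mouse or the handling of the tissue lowered the fatty acid oxidation transcripts remains open and was not tested.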
